A study of Homo sapiens with 4 samples.

How the data were processed

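RNA from DU-145 cells, an established prostate cancer cell line, was compared on 4 two-colour Agilent arrays, each hybridised with RNA of treated cells in one dye and RNA of untreated cells in the other. The treatment was 5-Aza (5-Aza-2'-deoxycytidine, also called decitabine), a cytosine analogue that is built into DNA and traps DNA methyltransferases, so that DNA methylation is lost as cells divide. Dose and duration are not given in the labels used here. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase and amplified and labelled with an Agilent linear amplification kit. Arrays 1 and 3 held the treated RNA in Cy3, and arrays 2 and 4 held it in Cy5. The submitters' design text states 2 biological and 2 technical replicates. The labels do not say which arrays shared an RNA extract.

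The deposited table holds 1 value per feature and array, read here as a log2 ratio. Per the submitters' processing notes, the scanner images were read with Agilent Feature Extraction 9.5. The background correction, the normalization and the filter on features are not given in the sources used here. The table lists 24581 features, of which 13111 have a value on all 4 arrays and 11470 are blank on all 4. The log base is unstated. The values reach 7.36, which on a log10 scale would exceed the range of the scanner. The values were therefore treated as log2, the usual base for such tables. A natural log is not excluded, and all fold statements would then be larger, while p-values and counts of calls do not depend on the base. The array medians lay between -0.04 and 0.02, close to centred. Scanner intensities were not used here, so no feature can be judged against its background and no limit on precision other than the number of arrays can be given. No 2 arrays held identical values.

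The direction of the ratios is also unstated. All 6 pairs of arrays correlated above 0 across features although the dyes were swapped on 2 arrays, so the ratios were taken as already turned one way. The sample descriptions name treated before untreated on all 4 arrays, those with swapped dyes included. Treated over untreated is therefore the likely direction, and "higher" below means a positive deposited ratio. The other reading, in which the ratios follow the dyes and were not turned, was run as an alternative.

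The tables used here do not pair the feature numbers with genes. The 23 gene lists fixed before the data were examined, the comparison of non-coding with protein-coding probes and the gene-level fits were therefore not run. The rule for named items, also fixed before the data were examined, left 4 features to be named by number: the 2 largest mean ratios in each direction with one sign on all 4 arrays.

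The main test was fixed before the data were examined and was run with limma 3.58.1 in R 4.3.3. Each treated-in-Cy3 array was averaged with a treated-in-Cy5 array, which gives 2 replicates and cancels the dye effect, and the mean was tested against 0 with a moderated variance. As the true pairing is unknown, this was done for both dye-swapped pairings, and the larger p was adjusted by the Benjamini-Hochberg method over 13111 features, with calls at an adjusted p under 0.05. This assumes that the technical replicate of an array is its dye swap. Further settings fixed in advance were the 4 arrays as separate replicates, the same with a dye term, each of the 3 pairings alone, all 3 pairings together, the pair as a random block, centring on the median or on a trimmed mean, scale and quantile normalization between arrays, a robust variance prior, stricter thresholds and leaving out each array. P-values over 4 separate arrays measure the spread between arrays, part of which is technical. They rest on 4 arrays from 2 biological replicates, count technical replicates as independent and can therefore be too small. Added after seeing the data were the count of features with a mean ratio of at least 1 in size and one sign on 4 arrays, the removal of features near the array edge, a local correction by position, and the reading as ratios not yet turned.

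Feature numbers were read as places on the array in rows of 85. Deviations from the feature mean correlated between features 85, 170 and 255 numbers apart, with a mean over arrays of 0.074, 0.097 and 0.076, against at most 0.030 at 346 lags away from neighbours. The highest feature number, 45220, makes 532 such rows. Outer positions are the first and last 5 of a row, which hold 1488 features. The local correction subtracted from each value the median of features within 10 rows and 2 positions on the same array.

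The tests were tested on simulated data of 13111 features, 4 independent arrays and 200 changed features. Each feature's SD over the 4 real arrays was taken as its true SD. Such an SD varies by chance, so the simulated variances are likely more uneven than the true ones. The main test called 0 of 67 features changed by 1, 0 of 67 changed by 2 and 0 of 66 changed by 4 on the log2 scale. Over 4 separate arrays, the fit called 30 of 67, 48 of 67 and 63 of 66 of them, and 6 of the 12911 unchanged features. With a dye term it called 3 of 67, 38 of 67 and 55 of 66, and 2 unchanged features. The main test gave an unadjusted p under 0.05 to 332 of the unchanged features. The simulated arrays shared no extract and held no dye effect. These counts therefore need not hold for the real design of 2 biological and 2 technical replicates.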

Results

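The series compared RNA levels in DU-145 prostate cancer cells treated with the demethylating agent 5-Aza with those in untreated cells, on 4 two-colour arrays from 2 biological replicates. The comparison asks which transcripts, coding and non-coding, differ in abundance after treatment. A ratio was listed on all 4 arrays for 13111 features, which is 53.3% of the 24581 in the table. Features are identified by number only, and no gene name is paired with them in the tables used here, so the results are given for features and not for genes. A positive ratio is likely higher in treated cells, because the sample descriptions put treated before untreated on every array, but the table itself does not state it.

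The ratios of the 4 arrays agreed in part. Across features, the Pearson correlation was 0.316 ± 0.063 (SD over 6 pairs of arrays), with a range from 0.243 to 0.415. The mean Spearman correlation was 0.253. Arrays with the same dye orientation correlated at 0.338 and 0.415, and the 4 pairs with swapped dyes at 0.243 to 0.344. These correlations are across features, which are not independent replicates. The ratio had one sign on all 4 arrays for 3976 features (30.3%), where 4 independent arrays would give 12.5%. Arrays that share an RNA extract are not independent, and extracts shared between arrays raise this share whether or not the treatment had an effect. Of these, 1975 were higher and 2001 were lower.

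**Figure D1:**
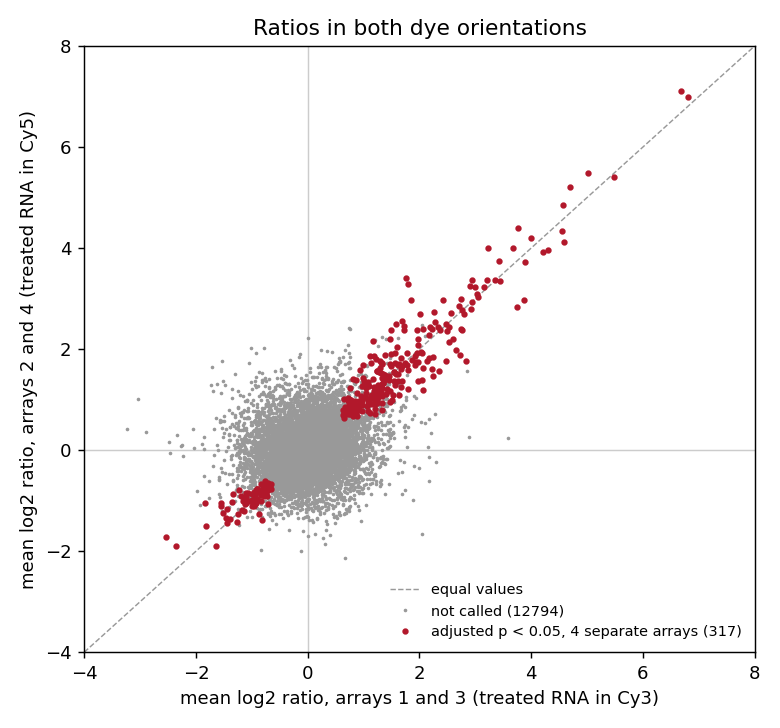
Mean log2 ratio of each of the 13111 features on the 2 arrays with treated RNA in Cy5 (vertical axis) against the 2 arrays with treated RNA in Cy3 (horizontal axis). Red points are the 317 features with an adjusted p under 0.05 when the 4 arrays are taken as separate replicates; the largest positive ratios lie near the dashed line of equal values in both dye orientations.

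Large ratios were mostly positive. With one sign on all 4 arrays, 303 features had a mean log2 ratio of 1 or more and 65 had one of -1 or less. The imbalance grew with size, to 70 features at 2 or more against 2 at -2 or less. At 3 or more there were 27 features, and 12 of these reached 4, with 0 at the same sizes in the negative direction. On each array alone the count at 2 or more was above the count at -2 or less. The counts were 169 against 35 on array 1, 128 against 18 on array 2, 103 against 39 on array 3 and 123 against 19 on array 4. These counts asked nothing of the other arrays and include features at the array edge, described below for arrays 1 and 3. Arrays that share an extract are also not independent. The imbalance per array was given no test. A two-sided exact sign-flip test cannot give a p below 0.125 over 4 arrays, or below 0.5 over 2 biological replicates.

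Changing the signs of 2 of the 4 arrays removes what is common to all arrays. The 3 ways of doing so counted 61, 47 and 22 features of at least 1 in size with one sign, against 368 as deposited. These are other features, because one with a single sign on all 4 arrays cannot have it after the change. The 368 drop out by the counting rule, so the lower counts are no test of them. None of these 3 patterns had more than 1 feature of 2 or more. The pattern with 61 features is the one that follows the dyes.

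**Figure D2:**
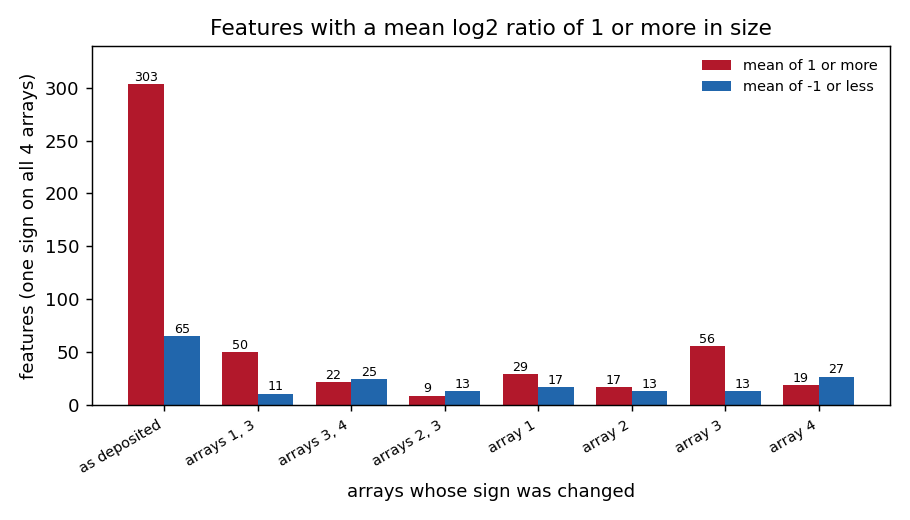
Number of features with a mean log2 ratio of 1 or more (red) or -1 or less (blue) and one sign on all 4 arrays, as deposited and after the sign of the named arrays was changed. The deposited ratios gave 303 and 65 features, and the highest total of any other pattern was 69. Features counted as deposited cannot have one sign after the change, so the other bars count other features.

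The main test, limma on 2 averaged dye-swapped pairs, called 0 of 13111 features after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.109. At an unadjusted level of 0.05, 1696 features passed, 961 higher and 735 lower, where a uniform p would give 656. In simulated data, 332 of 12911 unchanged features passed at that level, as the larger of the p-values of both pairings was taken. The simulated arrays shared no extract, so 332 is not the error rate for the real arrays. With 2 replicates the main test also called 0 of the simulated features changed by 4 on the log2 scale, so the count of 0 does not show that levels were equal. That count also rests on the assumed dye-swapped pairs. The same-dye pairing of arrays 1+3 and 2+4 alone called 52 features, all higher. With the 4 arrays as separate replicates, limma called 317 features, of which 246 were higher and 71 lower, and 2548 passed at the unadjusted level. Their median absolute log2 ratio was 1.25, the smallest was 0.64, and all 317 had one sign on the 4 arrays. A dye term in the model lowered the count to 116, of which 107 were higher and 9 lower, and 112 of them were among the 317. The dye term itself was called for 0 features by limma, with 1207 at the unadjusted level. Both fits over separate arrays count technical replicates as independent, so their p-values can be too small and their counts too high.

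The count over separate arrays fell when any 1 array was left out, with fewer degrees of freedom and unbalanced dyes by construction. It was 67 without array 1, 46 without array 2, 43 without array 3 and 69 without array 4. Without array 3, 41 of the 43 were among the 317, and in the other fits all were. In all, 35 features were called in each of these 4 fits, and all 35 were higher. If the deposited ratios followed the dyes and had not been turned, the treatment would lie in the part that changes sign with the dye, and limma then called 0 features in either fit. At the unadjusted level 612 passed in averaged pairs and 693 over 4 separate arrays.

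The 2 largest positive ratios belonged to features 37473 and 26652. Feature 37473 had a mean log2 ratio of 6.90 ± 0.23 (SD, n = 4 arrays) and feature 26652 one of 6.89 ± 0.39 (SD, n = 4 arrays). On a log2 scale both are about 119-fold. In averaged pairs the limma adjusted p was 0.109 for each, which did not pass. Over 4 separate arrays it was 0.00035 for feature 37473 and 0.00040 for feature 26652, and 0.0049 for both with a dye term. Those fits count technical replicates as independent, so these values can be too small. The 2 most negative ratios with one sign were smaller in size. Feature 41403 had a mean of -2.13 ± 0.66 and feature 31042 one of -2.12 ± 0.28 (SD, n = 4 arrays), or 4.36-fold lower for each on a log2 scale. The limma adjusted p in averaged pairs was 0.30 for feature 41403 and 0.20 for feature 31042. Over 4 separate arrays it was 0.030 and 0.0054. With a dye term it was 0.059 for feature 41403, which no longer passed, and 0.020 for feature 31042. None of the 4 lay in the outer positions of the array.

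Single arrays held features far from the others, and many of these lay at the edge, with the largest shares on arrays 1 and 3. A distance of at least 2 on the log2 scale from the median of the other 3 arrays was found for 209 features on array 1, 139 on array 2, 167 on array 3 and 176 on array 4. The outer positions, which hold 11.3% of features, held 39.2% of them on array 1 and 36.5% on array 3. The shares were smaller on array 2, at 21.6%, and on array 4, at 22.7%. The highest share among 10000 random sets of as many features was 22.5%, 21.6%, 20.4% and 21.0% for arrays 1 to 4. On array 1, 58 of the far features in the first 5 positions were above the other arrays and 6 below. On array 3, 3 were above and 26 below. Without the outer positions, 263 of the 303 large higher and 60 of the 65 large lower features were left, and the count over separate arrays was 320.

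**Figure D3:**
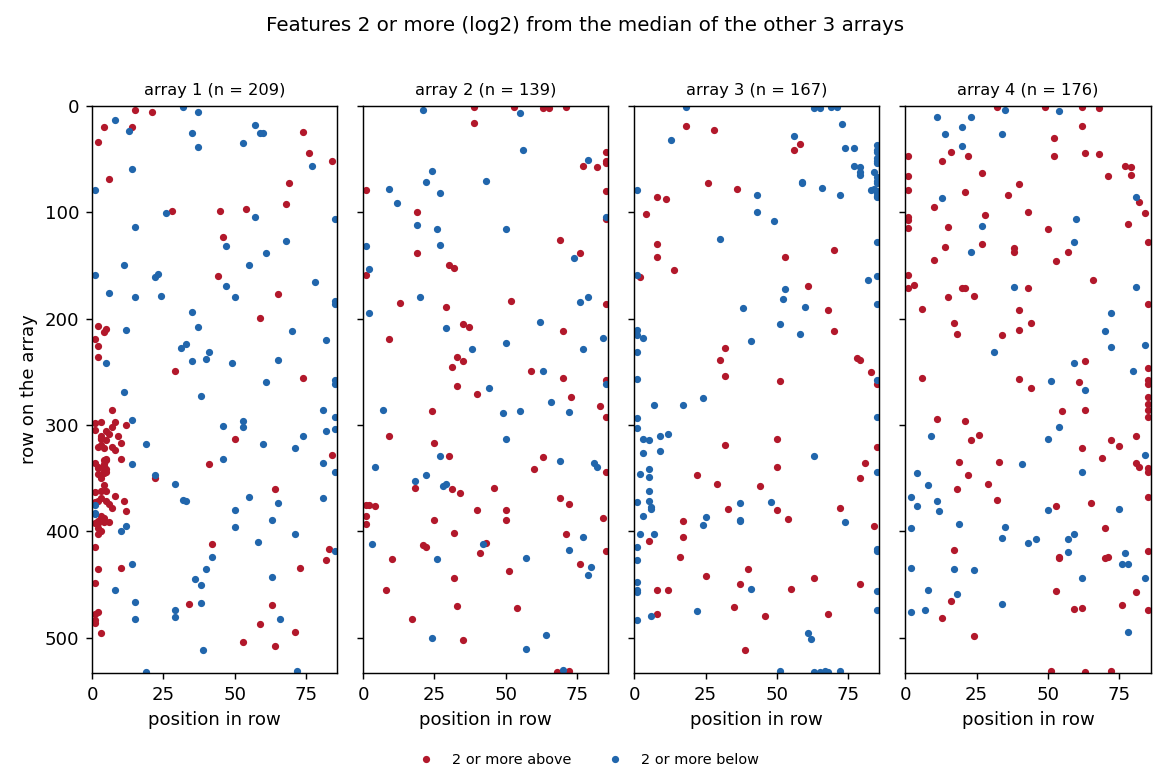
Place on the array, as row (vertical axis) and position in the row (horizontal axis), of features whose log2 ratio was at least 2 above (red) or below (blue) the median of the other 3 arrays, for arrays 1 to 4. Array 1 has a cluster of red points at the first positions, and array 3 has blue points along both edges.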

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

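All tests in this part were chosen after the results were seen. Of 13 array-level and feature-level measures checked for 1 array standing apart, 1 was marked, and chance alone marks about 1 in 20. Array 3 had 12 features at -3 or less, against 1 on array 1 and 0 on arrays 2 and 4. All 12 lay at the last position of a row, between rows 37 and 86. Their mean was -4.38 on array 3, against -0.33, 0.44 and -0.07 on arrays 1, 2 and 4.

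A true difference between treated and untreated cells in the RNA on array 3 would have to appear on the array that carries the same extracts, which by the stated technical replicates is 1 of the other 3. The lowest mean of these 12 features on another array was -0.33, on array 1, with a standard error of 0.19 over the 12 features, against -4.38 on array 3. This argues against a treatment difference in these extracts as the source of the 12 values. A defect tied to the position on single arrays, such as uneven hybridisation or washing, is a candidate explanation. The outer positions held 39.2% of far spots on array 1 and 36.5% on array 3, above the highest random shares of 22.5% and 20.4%. Array 4, at 22.7%, also lay above its highest random share of 21.0%, and array 2, at 21.6%, equalled its own. The type of defect, and whether part of the other far spots differ for another reason, stay open, because intensities and images were not used here.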

How the results depend on the processing

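The main count of 0 stayed 0 under 17 of 24 alternatives. Some of these could only give 0. They asked for a stricter threshold, a minimum size or one sign on top of the same calls, or for the same-dye pairing too. It became 317 over 4 separate arrays, 116 with a dye term, 52 with the same-dye pairing of arrays 1+3 and 2+4 alone, and 8 after the neighbours' median was subtracted. With the pair as a random block it was 824 for arrays 1+2 and 3+4, 1679 for arrays 1+4 and 2+3 and 305 for the same-dye pairs. The first 2 of these used within-pair correlations of -0.28 and -0.46, that is, members of a dye-swapped pair deviated in opposite directions. The 1696 features at the unadjusted level became 2753 with arrays 1+4 and 2+3 as the only pairing, and ranged from 1086 to 1388 when 1 array was left out. The 317 calls over separate arrays became 116 with a dye term, 70 at an adjusted p under 0.01, and 218 when a mean ratio of at least 1 was asked for too. Leaving out 1 array gave 43 to 69, with fewer degrees of freedom by construction. Centring, scale and quantile normalization, the robust prior and both corrections for position kept this count between 282 and 327. Read as not yet turned, the ratios gave 0 calls over separate arrays and 612 features at the unadjusted level in averaged pairs. That reading counted 50 and 11 large features, none of them among the 303 and 65. The 65 large lower features ranged from 72 to 107 when 1 array was left out, where one sign was asked of 3 arrays only. The mean correlation of 0.316 became 0.638 for features with a mean over 0.5 in size, which were chosen on the same arrays. Where no value above explains a change, the cause was not tested. The 4 named features passed the threshold in 23 of 80 fits and kept their sign in each. None of the 80 read ratios as not yet turned. Choosing them for one sign on 4 arrays largely fixed the sign. Their limma adjusted p ranged from 6.4e-05 to 0.208 for feature 37473 and from 0.00013 to 0.208 for 26652. It ranged from 0.0084 to 0.522 for 41403 and from 0.0011 to 0.368 for 31042. Not run were the alternative on missing values, since no feature is listed on some arrays only, and those that need gene names, intensities or slides. The number of arrays and of biological replicates limits every call.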

Other observations

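Other than the fit over 4 separate arrays, which was fixed in advance, the tests in this part were chosen after the results were seen. The balance of higher and lower features depended on their size. All features with one sign on all 4 arrays, large ones included, were 1975 higher and 2001 lower. The array medians lay close to 0, which by itself brings these counts near each other. Of these features, 303 higher and 65 lower were 1 or more in size, so the smaller ones leaned to lower. Those with a mean of 2 or more in size were 70 higher and 2 lower. The median SD over 4 arrays was 0.40 for the 70 features at 2 or more, 0.52 for the 261 from 1 to 2, 0.52 for the 80 at -1 or less and 0.33 for the 12700 between -1 and 1. Across features, 32.9% of the variance of a single array was shared by all 4 arrays, 4.43% changed sign with the dye and 62.6% was neither.

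Gain of transcripts after loss of DNA methylation is a hypothesis that the treatment names for the excess of large positive ratios, and no test here bears on it without gene names. The array edge does not account for the excess. Without the outer positions, 69 features stayed at 2 or more and 2 at -2 or less. An offset of 0.225 in the centring of the arrays does not account for the excess at 2 or more. After lowering all ratios by 0.225, which brought the counts to 205 at 1 or more and 212 at -1 or less, 59 features still lay at 2 or more against 3 at -2 or less. For the excess at 1 or more the centring stays open, because the unstated normalization fixes where 0 lies. The deposited ratios alone cannot show whether it is off by 0.225. Equal counts at 2 or more and -2 or less took a shift of 0.81, and an offset of that size was not excluded either. With no demand on the sign of single arrays, a change of sign of 2 arrays gave at most 1 feature at 2 or more and a change of sign of 1 array, which keeps part of any shared difference, gave at most 13, against 70 as deposited. All 70 had one sign on the 4 arrays, so a change of sign lowers their means by construction. The lower counts are therefore no test of the excess. The real arrangement was also 1 of 8, so the share cannot fall under 0.05. A floor set by background on weak signals may also limit negative ratios more than positive ones, and without intensities it stays untested.

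Over separate arrays, limma called 317 features as deposited and 0 in each of the other 7 sign patterns (splits of the 4 arrays by sign). In those patterns 324 to 693 features passed at an unadjusted 0.05, against 2548 as deposited. All 317 had one sign on the 4 arrays, so a change of sign turns their shared difference into spread. The drop in calls was therefore largely built in and is no separate support for them. The 8 patterns are also too few for a share under 0.05, and the real pattern was the 1 that gave 317 calls. Whether the part shared by all arrays is treatment or dye bias rests on the ratios having been turned before deposit. If they were not turned, the shared part could be dye bias, and 15 features of at least 3 on the log2 scale on every array would then have to differ by dye alone. No table used here gives the size that a dye bias can reach, so a turn before deposit stays likely and not settled. Whether a positive ratio means treated over untreated is a separate question. It rests on the order in the sample descriptions and is likewise not settled.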
